A study of Mus musculus with 13 samples.

How the data were processed

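The samples were aortae of C57BL/6 mice, an inbred laboratory strain. Per the labels, the mice were kept for 2 weeks in a cycle of 12 h of light and 12 h of darkness and then for 36 h in constant darkness, after which aortae were taken every 4 h over 48 h. Aortae of 6 mice were pooled at each of 12 time points, named by circadian time (CT) from CT18 to CT62, and biotin-labelled probe made from each pool was hybridised to a one-colour array of short oligonucleotides. There were 13 arrays, because CT18 had a duplicate array. The labels do not say whether the pair came from the same pool; it was counted as 1 pool. The number of arrays limits the precision of every value.

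The values analysed were the deposited intensities, 1 per probe set and array, on a linear scale. The software that made them and its scaling are not given in the sources used here. In the deposited table the mean intensity left after trimming 2% of probe sets at each end was 200.2 on every array, so the authors' values were treated as already scaled and were used as deposited. Between 21.3% and 24.2% of the intensities of an array were at or below 0, and these values have no logarithm. The median intensity of an array lay between 70.4 and 87.6, and the 5th percentile between -152 and -69.2. RNA quality was read from control probe sets. The ratio of 3' to 5' signal was 1.64 to 2.21 for actin and 1.05 to 1.31 for Gapdh.

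The table held 12488 probe sets, of which 66 were hybridisation controls and were left out. A platform annotation table paired 10833 of the other 12422 with 1 gene, 396 with several genes, and did not list 1193. Symbols were checked by gene identifier against a RefSeq table of mouse assembly GRCm38.p6, which held 10817 of the 10833 and changed 0 symbols. The build used in the design of the array is not given in the sources used here, so no positions are given. Probe sets with several genes or none stayed in the tests under their identifier.

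Intensities below 36.7, the 20th percentile of all positive values, were set to that floor, and log2 was taken. The duplicate CT18 arrays were averaged on the log2 scale. Probe sets whose mean over the 12 pools was at or above the 40th percentile of such means (log2 of 5.60, an intensity of 48.5) were kept, which left 7453 probe sets and 5655 genes. A gene with several probe sets was represented by the one with the highest mean. Values at the floor are bounds, and folds against them are given as "at least".

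Rhythms were fitted with limma 3.58.1 in R 4.3.3. The cosine and sine of a 24-h period were fitted to the 12 pools (9 residual degrees of freedom), and a moderated F test with an intensity trend in the variance (eBayes, trend) was adjusted by the Benjamini-Hochberg method over the probe sets kept, with a threshold of 0.05. The amplitude is the distance from the mean to the peak on the log2 scale, and the peak is given in hours of circadian time. Amplitudes carry the SE of the fit over 12 pools. The same framework tested a term for the second day (CT42 to CT62) against the first (CT18 to CT38), a 12-h component, and a difference in rhythm between the days, each with the lower terms as covariates (8, 7 and 6 residual degrees of freedom). Each time point was 1 pool, so p-values measure the spread of pools around the fitted curve.

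Before the data were examined, 24 gene lists were fixed. The mean centred profile of each list with at least 3 genes kept (23 lists) was tested by the R2 of a 24-h cosine. Its p came from 100000 permutations of the time points, one-sided and adjusted over lists. With covariates a partial R2 is given, the share of the variation that the covariates leave over. It does not compare with an R2 without covariates. Members past the threshold were counted over all probe sets and adjusted over the list alone, and one-sided Fisher's exact tests compared them with the other genes. The Fisher tests ignore the correlation between genes and serve as a description. Day effects of lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation. Pools were also compared by the correlation of their centred profiles according to hours apart, with a one-sided permutation test of 24 h against 12 h apart.

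The rule for the genes named was fixed at the same time: every measured member of the 3 clock lists; the 20 genes with the largest amplitude among those past the threshold whose peaks fitted on each day alone lay within 4 h; and, for each other list, up to 4 members past the threshold by smallest p, or the 1 with the smallest p where none passed. For the day, 12-h and interaction tests, the 3 genes with the smallest p were named where none passed.

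The procedure was tested on simulated data in which 100 probe sets of each size were given a known effect. It recovered 49% of rhythms of amplitude 0.5 and 78% of amplitude 1, with 6 false calls among 7453 probe sets. It recovered 23% and 64% of day differences of these sizes, 47% and 76% of 12-h components, and 2% and 18% of differences in rhythm between days. In 200 simulated lists with no rhythm, 4.5% had a p below 0.05. The simulated noise was independent between genes and had no floor, unlike the real data, so these rates may not hold for them.

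Alternatives set before the data were examined were quantile normalization, centring of arrays on their medians, other floors (5th and 40th percentiles) and filters (none, 60th percentile), other variance models, array weights, removal of probe sets marked for cross-hybridisation, periods of 22 h and 26 h, a drift or day covariate, paired differences between pools 24 h apart for the day test, a rank test, 13 arrays as separate samples, and leaving out each time point or CT18 array. Alternatives added after the data were seen were covariates for array noise (log2 of the negative 5th percentile) and for markers of carried-over tissue, scaling on the 75th percentile, leaving out CT46 as the pool least like the others (already among the single time points), and leaving out the pools CT18, CT34 and CT58 together.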

Results

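Gene expression was measured in pooled mouse aortae at 12 time points 4 h apart, from CT18 to CT62, in constant darkness. The series spans 2 circadian cycles, with CT18 to CT38 on the first day and CT42 to CT62 on the second, so each of 6 circadian times was sampled by 2 pools 24 h apart. Each time point was analysed as 1 pool of 6 mice, without replicate pools. Of 12422 probe sets, 7453 passed the intensity filter. On an array, 4.01% to 6.02% of these were at the floor of measurement.

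The series addresses which aortic transcripts follow a 24-h rhythm when no light cycle is present. The clearest rhythm was that of Nr1d2 (probe set 99076_at), a nuclear receptor that represses clock genes. Its fitted amplitude was 1.72 ± 0.10 (log2, SE), with a peak at CT9.3 and an adjusted p of 1.19e-05. Its intensity at CT10 averaged 442 ± 66.3 (SD, n = 2 pools), at least 12.0-fold above CT22, where the mean of the pools was below the floor. Per2 (93694_at), a repressor of the clock's main activator complex, had an amplitude of 1.25 ± 0.14 and peaked at CT13.5 (adjusted p = 0.00897). Per2 lay at the floor in 3 of 12 pools, and its amplitude ran from 0.49 to 1.98 over the alternatives. Dbp (160841_at), a PAR bZIP transcription factor driven by the clock, peaked at CT8.5 with an adjusted p of 0.0410. Dbp averaged 443 ± 2.17 at CT10 (SD, n = 2) and lay at the floor in 7 of 12 pools, so its fitted amplitude of 1.95 ± 0.30 depends on the floor. Dbp passed in 11 of 34 alternatives, and in 5 of the 14 fits that left out a time point or a CT18 array.

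The other measured clock genes did not pass the threshold over all probe sets. Some passed in a minority of the alternatives, for example Nr1d1 after quantile normalization (adjusted p = 0.0392) and Cry1 with the filter at the 60th percentile (0.0406). Without CT30, Arntl, Nfil3 and Tef passed (0.0484, 0.0260 and 0.0385), and Arntl passed in no other alternative. Arntl (Bmal1), the partner of Clock in the activator complex, averaged 291 ± 24.4 at CT22 and 59.8 ± 20.1 at CT10 (SD, n = 2 each). Its fitted amplitude was 0.89 ± 0.18 with a peak at CT22.1 (adjusted p = 0.115). Cry1, another repressor, had an amplitude of 0.64 ± 0.11 and a peak at CT18.4 (adjusted p = 0.0604). Nr1d1 had 0.75 ± 0.13 and CT5.4 (adjusted p = 0.0627), and Tef, a PAR bZIP factor, had 1.26 ± 0.23 and CT10.5 (adjusted p = 0.0846). Nfil3, a repressor that binds the same sites as the PAR bZIP factors, had 1.36 ± 0.29 and CT21.3 (adjusted p = 0.140). The probe sets used for Cry1, Nfil3 and Rora are marked for cross-hybridisation. A further Nfil3 probe set without that mark had 1.13 ± 0.20 and CT19.0 (adjusted p = 0.0668). Clock had 0.37 ± 0.10 (adjusted p = 0.293) and Per1 0.65 ± 0.31 (adjusted p = 0.631). Per3, Cry2, Rora and Bhlhe40 had amplitudes of 0.07 to 0.18 with adjusted p from 0.821 to 0.948. Npas2 did not pass the intensity filter, and Bhlhe41, Ciart and Hlf were not analysed here.

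**Figure D1:**
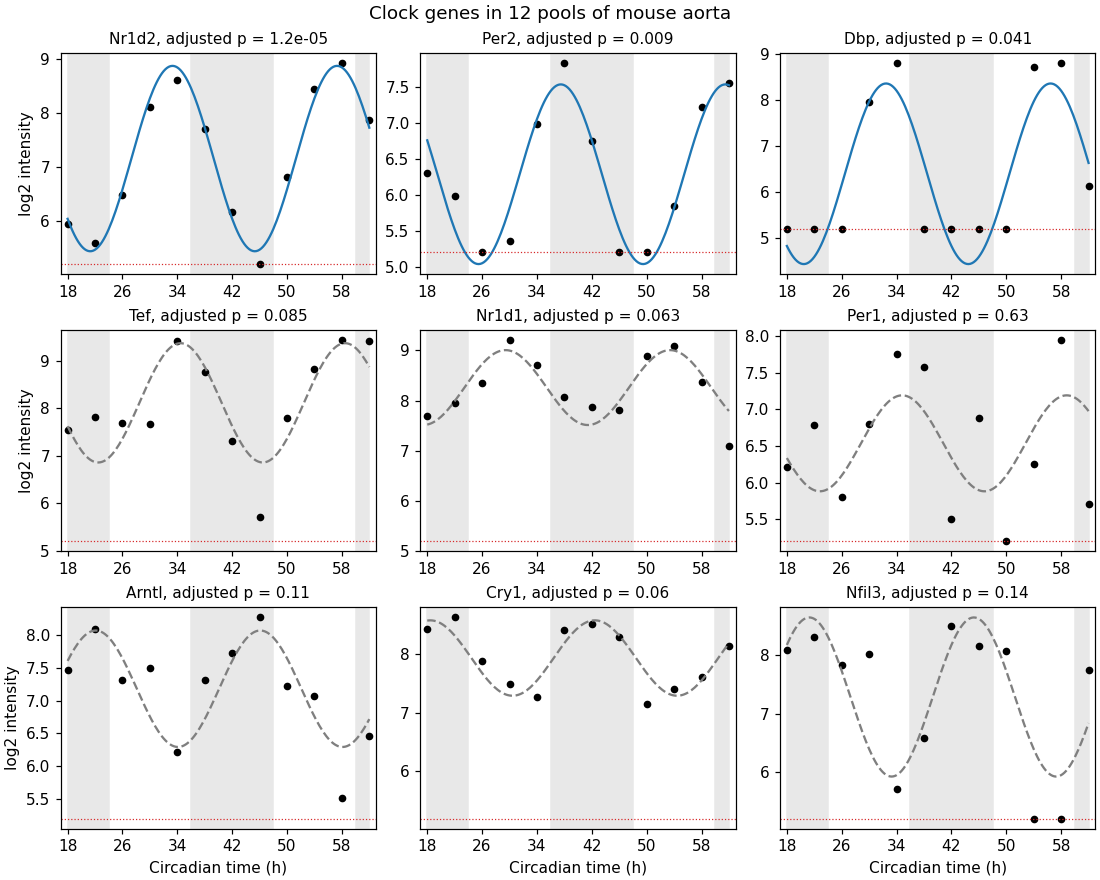
Each panel plots log2 intensity (vertical axis) against circadian time in hours (horizontal axis) for 1 clock gene in the 12 pools, with each point 1 pool (CT18 is the mean of 2 arrays). Lines are fitted 24-h cosines, solid where the adjusted p passed the threshold and dashed where it did not, the dotted line is the floor, and grey marks the hours of subjective night; Nr1d2, Per2 and Dbp, in the top row, are the genes that passed.

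As groups, all 3 clock lists had a rhythmic mean profile. The mean profile of the 8 measured core repressors had an amplitude of 0.34 ± 0.05 (SE) and a peak at CT11.1 (R2 = 0.818, adjusted permutation p = 0.0251), and 2 members passed over all probe sets against 4 adjusted over the list alone. The mean of the 3 measured activators peaked at CT21.4 (amplitude 0.38 ± 0.09, adjusted permutation p = 0.0487), with 0 members passing and 2 adjusted over the list alone. That of the 3 PAR bZIP and Nfil3 genes peaked at CT9.2 (0.58 ± 0.13, adjusted permutation p = 0.0487), with 1 passing and 3 adjusted over the list alone. Nfil3 had its peak near the trough of Dbp and Tef, so that mean combines opposite profiles, as does that of the repressors, where Nr1d1 peaked at CT5.4 and Cry1 at CT18.4. Leaving out a single time point moved the number of lists with a rhythmic mean from 6 to between 0 and 6, and centring arrays on their medians left 1, the core repressors. With the tissue markers as covariates none of the clock lists passed. The adjusted permutation p was 0.0911 for activators and repressors and 0.0796 for PAR bZIP and Nfil3 genes. The partial R2 was 0.746, 0.757 and 0.815.

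In total 26 probe sets passed for a 24-h rhythm. They covered 23 genes and 3 probe sets that the annotation table did not list (99019_at, 94507_at and 104745_at). Amplitudes ran from 0.35 to 1.95 with a median of 0.57. Of the 26 peaks, 5 fell between CT0 and CT6, 11 between CT6 and CT12, 4 between CT12 and CT18, and 6 between CT18 and CT24. In all 26 the peaks fitted to each day alone lay within 4 h of each other. The 26 had been picked by a fit to both days together, which favours such agreement, so this adds no independent evidence. At an unadjusted p below 0.05 there were 742 probe sets (9.96%), where chance gives 372.7. The count was 8 to 40 when 1 time point was left out, 5 after centring arrays on their medians and 0 with the rank test. Nr1d2, Per2, Hspa8, Eln and Cebpa passed in all 14 fits that left out a time point or a CT18 array.

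**Figure D2:**
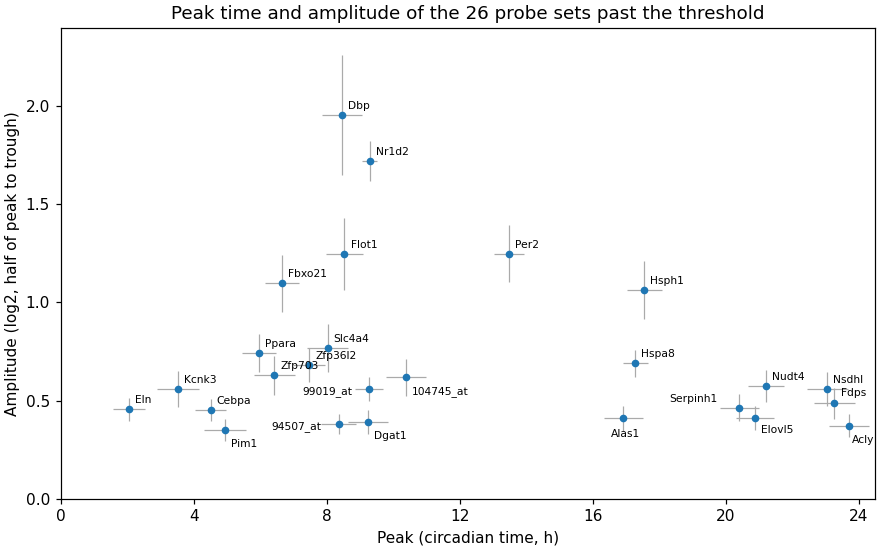
Each point is 1 of the 26 probe sets past the threshold, placed by fitted peak in hours of circadian time (horizontal axis) and amplitude in log2 units (vertical axis), with bars for the SE of each. Amplitudes run from 0.35 to 1.95, and 11 of the 26 peaks lie between CT6 and CT12.

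Some rhythmic genes encode transcription factors, enzymes, or regulators of RNA and protein turnover, groups that were not tested as such. Ppara (102668_at), the nuclear receptor that controls fatty acid oxidation, rose to 985 ± 4.39 at CT6 from 424 ± 119 at CT18 (SD, n = 2 each; adjusted p = 0.0173). Cebpa (98447_at), a transcription factor of adipocytes, peaked at CT4.5 (amplitude 0.45 ± 0.05, adjusted p = 0.0101). Alas1, which makes the first committed intermediate of haem, peaked at CT16.9 (0.41 ± 0.06, adjusted p = 0.0410). Dgat1, an enzyme of triglyceride synthesis, peaked at CT9.2 (0.39 ± 0.06, adjusted p = 0.0460). Nudt4, a diphosphoinositol polyphosphate phosphatase, peaked at CT21.2 (0.57 ± 0.08, adjusted p = 0.0266), and Zfp36l2, an RNA-binding protein that promotes decay of messages, at CT7.5 (0.68 ± 0.09, adjusted p = 0.0130). Dimmer probe sets of Nudt4 (CT21.5, adjusted p = 0.419) and Zfp36l2 (CT8.3, adjusted p = 0.762) did not pass. Fbxo21, a subunit of ubiquitin ligases, had an amplitude of 1.10 ± 0.15 and a peak at CT6.7 (adjusted p = 0.0173). Zfp703, a zinc finger transcriptional repressor, had 0.63 ± 0.10 and CT6.4 (adjusted p = 0.0473).

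Further genes also passed the threshold. Eln (92836_at), which encodes elastin of the aortic wall, averaged 6509 ± 567 at CT2 and 3085 ± 180 at CT14 (SD, n = 2 each; amplitude 0.46 ± 0.06, adjusted p = 0.0130). A dimmer Eln probe set had an amplitude of 0.47 ± 0.11 and a peak at CT2.3 but did not pass (adjusted p = 0.183). Slc4a4, a sodium bicarbonate cotransporter, peaked at CT8.0 (0.77 ± 0.12, adjusted p = 0.0444), and Kcnk3, an acid-sensitive potassium channel, at CT3.5 (0.56 ± 0.09, adjusted p = 0.0484). Flot1, a scaffold protein of membrane rafts, peaked at CT8.5 (1.25 ± 0.19, adjusted p = 0.0364), with 3 pools at the floor and an amplitude of 0.55 to 1.66 over the alternatives, of which it passed 14 of 34. Pim1, a kinase (CT4.9, adjusted p = 0.0484), and Nsdhl, an enzyme of cholesterol synthesis, by a probe set that is not the brightest of its gene (CT23.1, adjusted p = 0.0457), also passed and are named outside the rule, after their values were seen. The brightest Nsdhl probe set had an adjusted p of 0.0975. Kcnk3 passed in 1 of 14 fits that left out a time point or a CT18 array, Fdps in 2, Zfp703 and Acly in 3 each, Dgat1 in 4, Slc4a4 and Alas1 in 5 each, Flot1 in 6, Elovl5 in 7, Nudt4 and Serpinh1 in 8 each and Fbxo21 in 10.

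**Figure D3:**
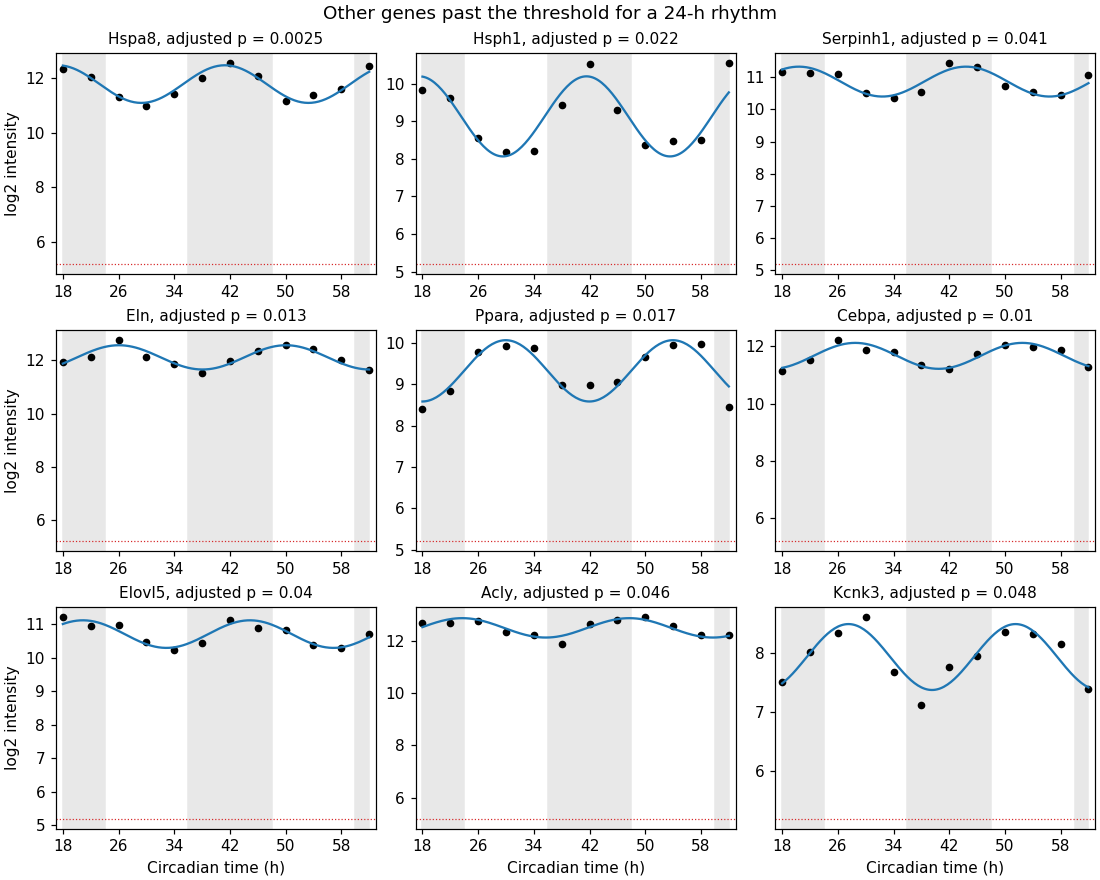
Each panel plots log2 intensity (vertical axis) against circadian time in hours (horizontal axis) for 1 of 9 further genes past the threshold, 1 point per pool (CT18 is the mean of 2 arrays), with grey for the hours of subjective night. Lines are fitted 24-h cosines and the dotted line is the floor; Hspa8 and Hsph1 peak near CT17, Eln near CT2 and Ppara near CT6.

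Heat shock and chaperone genes, which encode proteins that fold other proteins, were highest near the middle of the subjective night. Hspa8, a constitutive chaperone, averaged 5604 ± 588 at CT18 and 2364 ± 461 at CT6 (SD, n = 2 each), with an amplitude of 0.69 ± 0.07 and a peak at CT17.3 (adjusted p = 0.00255). Hsph1, its nucleotide exchange factor, peaked at CT17.5 (1.07 ± 0.15, adjusted p = 0.0222), and Serpinh1, the collagen chaperone of the endoplasmic reticulum, at CT20.4 (0.46 ± 0.07, adjusted p = 0.0407). Of the 28 members measured, 3 passed over all probe sets, a larger share than of the other genes (Fisher's exact test, adjusted p = 0.00189), and 12 passed adjusted over the list alone. The Fisher test treats genes as independent although they were measured in the same pools, so its p is only descriptive. The mean of the list peaked at CT17.7 with an amplitude of 0.31 ± 0.07 (R2 = 0.684, adjusted permutation p = 0.0487). Members passing within the list alone had peaks from CT16.3 (Dnaja1) to CT20.4 (Serpinh1), among them Stip1 (0.92 ± 0.17) and Hsp90aa1 (0.58 ± 0.12). Markers of skeletal muscle and thymus varied between the same pools. With these and atrial markers as covariates the list's adjusted permutation p was 0.0697. Its amplitude was then 0.61 ± 0.12 and its partial R2 0.862, which does not compare with the R2 of 0.684.

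Genes of cholesterol and fatty acid synthesis had a list mean whose fitted peak fell late in the subjective night, while its highest pools were CT18 (0.33) and CT46 (0.32). Elovl5, a fatty acid elongase, peaked at CT20.9 (amplitude 0.41 ± 0.06, adjusted p = 0.0402), Fdps, which makes farnesyl diphosphate, at CT23.3 (0.49 ± 0.08, adjusted p = 0.0484), and Acly, which makes cytosolic acetyl-CoA, at CT23.7 (0.37 ± 0.06, adjusted p = 0.0457). This Fdps probe set is marked for cross-hybridisation, and a dimmer one without that mark peaked at CT22.9 without passing (adjusted p = 0.143). Of 20 members measured, 3 passed over all probe sets (Fisher's exact test against the other genes, adjusted p = 0.00134, again only descriptive), and 10 passed adjusted over the list alone. The list mean peaked at CT22.1 with an amplitude of 0.26 ± 0.06 (R2 = 0.641, adjusted permutation p = 0.0487). The adjusted permutation p was 0.214 with array noise as a covariate (partial R2 = 0.49) and 0.139 with the markers of carried-over tissue (partial R2 = 0.668).

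The mean of the 20 immediate early genes, which respond within minutes to stimuli, peaked at CT4.5 with an amplitude of 0.21 ± 0.06 (adjusted permutation p = 0.0487). In this list 0 members passed over all probe sets and 3 adjusted over the list alone. These 3 were Nr4a1 (CT4.9), Klf6 (CT13.7) and Ccn2, a matricellular growth factor (CT17.5), so 2 of them did not share the peak of the mean. The list mean passed in 2 of 19 alternatives. Its adjusted permutation p was 0.317 with the tissue markers as covariates (partial R2 = 0.509) and 0.122 after centring arrays on their medians (R2 = 0.586).

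**Figure D4:**
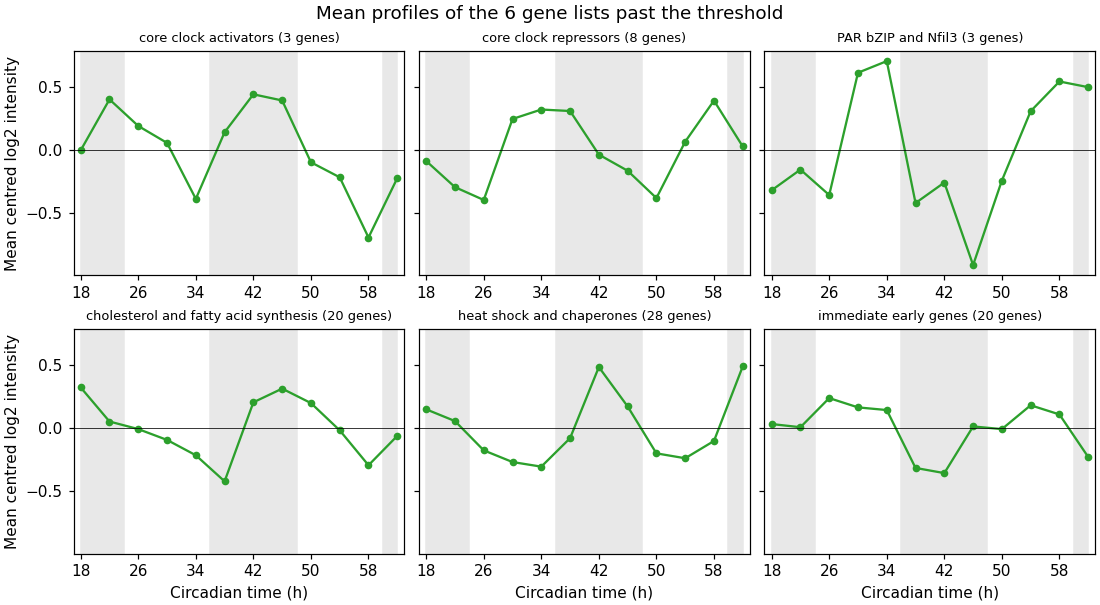
Each panel plots the mean centred log2 intensity of 1 gene list (vertical axis) against circadian time in hours (horizontal axis), 1 point per pool, with grey for the hours of subjective night; these are the 6 lists whose mean passed. Heat shock and chaperone genes were highest in the pools CT42 (0.49) and CT62 (0.49), and core repressors in CT58 (0.39).

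The other lists had no rhythmic mean past the threshold. In the adipocyte and perivascular fat list the mean did not pass (R2 = 0.276, adjusted permutation p = 0.339), with 1 of 20 members passing over all probe sets (Cebpa) and 7 adjusted over the list alone. Those 7 had peaks from CT4.5 (Cebpa) to CT17.5 (Lep). The smooth muscle contractile list gave R2 = 0.0958 (adjusted permutation p = 0.687), with 0 of 13 passing over all probe sets or adjusted over the list alone; its lowest p was that of Acta2, smooth muscle actin (0.22 ± 0.08). Endothelial markers gave an adjusted permutation p of 0.251, with 0 of 13 passing and 1, the tight junction gene Cldn5 (1.27 ± 0.29, CT23.1), adjusted over the list alone. Vascular tone signalling gave 0.251 with 0 of 20 passing in either way (lowest p Nppa), and haemostasis and fibrinolysis 0.339 with 0 of 10 (Anxa2). Fibroblast and extracellular matrix genes gave 0.243 with 1 of 35 passing (Eln), and fatty acid oxidation and PPAR targets 0.205 with 1 of 23 (Ppara), in each case also 1 adjusted over the list alone.

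Among the remaining lists, antioxidant and detoxification genes gave an adjusted permutation p of 0.251 with 1 of 30 members passing (Alas1) and 3 adjusted over the list alone. Glucose metabolism gave 0.251 with 0 of 25 passing and 1, Pfkp, adjusted over the list alone. Glucocorticoid responsive genes gave 0.426 with 0 of 20 and 1 (Cebpb), and cell cycle genes 0.473 with 0 of 28 and 1 (Cdkn1c, an inhibitor of cyclin-dependent kinases). Inflammation and adhesion gave 0.972 with 0 of 15 passing in either way (lowest p Ccl11), and oxidative phosphorylation 0.670 with 0 of 27 (Cox6a2, a subunit of heart and skeletal muscle). The cold inducible list had 1 measured gene, Cirbp, with an amplitude of 0.36 ± 0.13 and an adjusted p of 0.483 over all probe sets (0.0418 for the list alone).

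Markers of skeletal muscle, thymus and cardiac atrium, tissues near the aorta, differed widely between pools. The lists that hold them had no rhythmic mean past the threshold. Rag1, a recombinase of developing lymphocytes, measured 1200 at CT18 and 1460 at CT54 but was at the floor at CT26 and CT42, an at least 39.8-fold range. Tnnt3, troponin T of fast skeletal muscle, measured 4278 at CT34 and 3133 at CT18 against 416 at CT54. Nppa, natriuretic peptide A of the cardiac atrium, measured 1435 at CT38 against 112 at CT54. The skeletal and cardiac muscle list had an adjusted permutation p of 0.339 and 0 of 30 members passing in either way (lowest p Tnnc1). The leukocyte list had 0.972 and 0 of 22, with 1, Cd74, adjusted over the list alone. Erythroid genes had 0.294 and 0 of 4 (lowest p Hbb-b2), and Schwann cell and nerve genes 0.670 and 0 of 9 (lowest p Mbp). Without the pools CT18, CT34 and CT58, the highest in skeletal muscle markers, 4 probe sets passed for a 24-h rhythm, and 2 of these were among the 26. CT34 and CT58 are both pools of circadian time 10, so this fit lacks that time and the fall cannot be ascribed to muscle. With means of the skeletal muscle, thymocyte and atrial markers as covariates 8 passed, 6 of them among the 26, and without CT46, the pool least like the others, 17 passed, 15 of them among the 26.

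**Figure D5:**
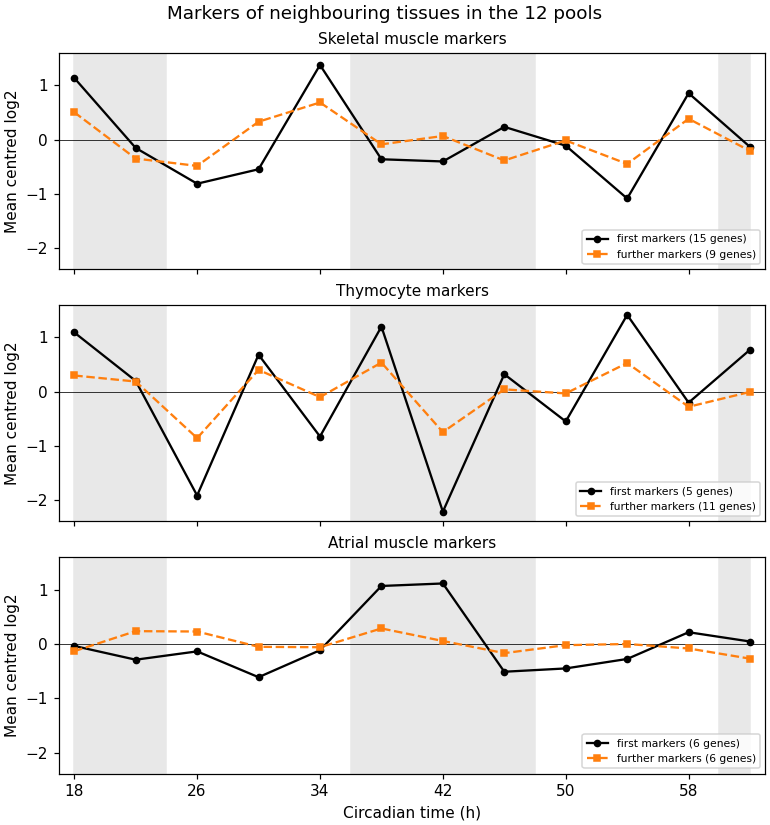
Each panel plots the mean centred log2 intensity of markers of 1 neighbouring tissue (vertical axis) against circadian time in hours (horizontal axis), 1 point per pool, with grey for the hours of subjective night. Black circles are markers picked after their values were seen and orange squares further markers picked before; the black skeletal muscle mean is 1.37 in the pool CT34 and the thymocyte mean is -2.21 in CT42.

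The comparison of the second day with the first asks whether levels drifted as the mice spent longer in darkness. With limma, 0 probe sets passed, and the lowest adjusted p was 0.416. The genes with the smallest p, none of them past the threshold, were Fcer2a, the low-affinity IgE receptor of B cells (second day minus first day -1.71 ± 0.30, log2, SE), Dpm1, a mannosyltransferase subunit (-0.54 ± 0.10), and Cdc42ep4 (-1.21 ± 0.24). Each was higher on the second day in 0 of the 6 pairs of pools 24 h apart. The second-day means of Fcer2a (5.43) and Cdc42ep4 (5.53) lay close to the floor (5.20, log2), so the sizes of these 2 differences may depend on the floor. At an unadjusted p below 0.05 there were 562 probe sets, 241 higher and 321 lower on the second day, where chance gives 372.7. Ordinary t tests, and paired differences between pools 24 h apart, also gave 0. Without CT42, 2 genes passed, Acvrl1 and Dpf2, named after their values were seen.

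As lists, 4 were higher on the second day by camera at the preset correlation, and 0 at an estimated one. Heat shock and chaperone genes had a median difference of 0.16 (adjusted p = 2.23e-06, and adjusted p = 0.643 with an estimated correlation). Adipocyte genes had a median of 0.07 (adjusted p = 0.00157, and adjusted p = 0.656 with an estimated correlation). Glucose metabolism also had a median of 0.07 (adjusted p = 0.00647, and adjusted p = 0.848 with an estimated correlation), as had cholesterol and fatty acid synthesis (adjusted p = 0.00719, and adjusted p = 0.848 with an estimated correlation).

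A 12-h component was tested because some transcripts have a peak in the morning and another in the evening. No probe set passed: with limma the count was 0, against 417 at an unadjusted p below 0.05, and the lowest adjusted p was 0.122. The smallest p belonged to Mrpl17, a mitochondrial ribosomal protein, with a 12-h amplitude of 0.75. Dbp had 0.97 and Slc35d1, a nucleotide sugar transporter, 0.64, both with an adjusted p of 0.426. Dbp lay at the floor in 7 of 12 pools and was high at CT6 (mean 332) and CT10 (443). A single peak cut off at the floor also yields a 12-h component, so its value does not show 2 peaks. An ordinary F test gave 1 (Slc35d1), and the fit with no intensity filter 1 (Lrp5). Without CT18, 3 genes passed (Nr4a1, Ckmt2 and Myl2), and without CT34 and without CT54 there was 1 each (Rps13 and Pfn1), all of these named after their values were seen.

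Whether rhythms differed between the 2 days was tested by an interaction. With limma 0 probe sets passed, 520 had an unadjusted p below 0.05, and the lowest adjusted p was 0.638. An ordinary F test also gave 0. Uggt1, a glucosyltransferase of glycoprotein folding, had the smallest p, with an amplitude of 0.91 and a peak at CT10.6 on the first day and 1.43 and CT22.1 on the second. Lonp1, a mitochondrial protease, and Aopep followed. The fitted second-day trough of Uggt1, around a mean of 6.21 (log2), lay below the floor of 5.20, so its amplitude may depend on the floor. The test recovered 18% of simulated differences of amplitude 1, so smaller differences were hardly detectable with 6 pools a day.

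Pools 24 h apart were compared with pools 12 h apart over all 7453 probe sets. The mean correlation of centred profiles was 0.0231 over 6 pairs 24 h apart and -0.123 over 9 pairs 12 h apart. The difference of 0.146 did not pass (permutation p = 0.0635, one-sided). Without the second CT18 array it was 0.155 (permutation p = 0.0373).

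The 2 CT18 arrays were the only ones that share a time point, and their difference includes variation between pools if they were not hybridised from the same one. Their log2 values differed with an SD of 0.372 per array over the probe sets kept. With the probe sets in 3 equal groups by mean signal, the SD was 0.486 in the dimmest, 0.380 in the middle and 0.182 in the brightest. The residual SD of pools around the fitted 24-h curve (root mean square) was 0.451 over all of them and 0.574, 0.441 and 0.295 in the same 3 groups. The duplicates correlated at 0.944 across probe sets, within the range of 0.878 to 0.949 of other pairs of arrays.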

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

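The alternatives named here were set before the data were examined, except the covariates for array noise and carried-over tissue, the scaling on the 75th percentile and the removal of CT18, CT34 and CT58 together. For the 24-h rhythm (26 probe sets), 5 passed after centring arrays on their medians, 4 with no filter, 3 with the floor at the 40th percentile, 4 without the variance trend, 4 with the ordinary F test, 12 with a linear drift, 0 with the rank test and 43 with 13 arrays as separate samples. Added alternatives gave 14 with array noise as a covariate, 8 with carried-over tissue, 4 without CT18, CT34 and CT58, and 7 with scaling on the 75th percentile. Leaving out 1 time point gave 8 to 40: 10 without CT18, 40 without CT30, 10 without CT34, 9 without CT42, 17 without CT46, 8 without CT54, 14 without CT58 and 13 without CT62. Other alternatives gave 18 to 37. Similar counts did not always hold the same probe sets. The periods of 22 h and 26 h gave 18 each, with 10 and 12 of them among the 26. Of the 40 without CT30, 20 were among the 26, and of the 14 with array noise, 10. Nr1d2 and Hspa8 each passed in 34 of 35 alternatives and Per2 in 30 of 34. All 3 were lost in the rank test (lowest adjusted p = 0.124), whose p-values are too coarse for a lone probe set to pass. Per2 was also lost with the floor at the 40th percentile, with carried-over tissue as covariates and without CT18, CT34 and CT58. Without 1 time point, Hsph1 was lost for CT42 (adjusted p = 0.0862), Zfp36l2 for CT54 (0.0536), and Ppara for CT18 and CT54 (0.0607 and 0.0543). Hsph1 and Zfp36l2 thus passed in 13 of 14 leave-out fits and Ppara in 12. Nr1d2, Per2, Hspa8, Eln and Cebpa passed in all 14, and the remaining genes past the threshold and named by the rule in 1 to 10.

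For the second day minus the first (0), 2 passed without CT42 and 1 with carried-over tissue as covariates, the range over leave-outs being 0 to 2. For the 12-h component (0), 1 passed with no filter and 1 with the ordinary F test, and leave-outs gave 0 to 3: 3 without CT18, and 1 each without CT34 and CT54. For rhythms that differ between days (0), 1 passed with the floor at the 40th percentile, and leave-outs gave 0. Of the gene list profiles (6 lists), 1 passed after quantile normalization, 1 after median centring, 0 with carried-over tissue as covariates, 1 with array noise, 0 without CT18, CT34 and CT58, and 0 to 6 without 1 time point: 0 without CT22, CT34, CT42, CT50, CT54 or CT58, 1 without CT26 or CT46, and 2 without CT30 or CT62. The core repressors passed in 11 of 19 alternatives, the other 5 lists in 2 to 5 each. The gene list day effect (4 lists) fell to 0 with an estimated correlation. The difference between pools 24 h and 12 h apart was 0.142 without CT18 replicate 1 and 0.155 without replicate 2, where it passed. The SD of the CT18 duplicates was 0.314 with no filter and 0.367 after quantile normalization. The cause was not tested. A fit of the differences between pools 24 h apart gave 0 for the day (lowest adjusted p = 0.371). Pairing by replicate number could not be fitted, since only CT18 has more than 1 array.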

Other observations

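Probe sets of several fat genes, including genes of brown fat, were bright at every time point. Intensities of different probe sets do not rank amounts of transcript. The tissue covariates held no fat markers. Whether a rhythm, such as that of Cebpa, arose in fat or in the aortic wall was not tested. Ucp1, the uncoupling protein of brown adipocytes, averaged 7666 ± 1590 (SD, n = 12 pools) and was never below 5898. Cidea, a lipid droplet protein abundant in brown fat, averaged 8858 ± 797, and Cox8b, a cytochrome oxidase subunit of brown fat and muscle, 8290 ± 939. Adipoq, the hormone adiponectin, averaged 8928 ± 576, and Scd1, a fatty acid desaturase, 18990 ± 1261. Other fat genes had dimmer probe sets. Elovl3, a fatty acid elongase of brown fat, ranged from 20.4 to 82.4. Dio2, a deiodinase that activates thyroid hormone, ranged from 152 to 652, and leptin (Lep) from 107 to 648. Pck1, an enzyme of glyceroneogenesis in fat, ranged from 1427 to 6322 with a fitted peak at CT5.8, and passed only adjusted over the list alone.

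Tests of marker genes against markers not looked at before, and the count over other orders of the pools, were set before their results were seen. All other tests of explanations in this part were chosen after the values behind them had been seen, and the first marker lists were picked after theirs. The count after median centring and the fits of the fixed lists without covariates had been set before the data were examined. The criteria of both tests on array medians were changed once more after their results were seen.

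The count of rhythmic probe sets exceeded that of every random order of the pools that was drawn. Of 100 orders of the 12 pools, 1, the real one, gave as many as 26, and the highest of the others gave 2. A chance order is thus an unlikely source of the count under the main settings. The comparison says nothing about any single gene among the 26. For the second day against the first, the real split gave 0, so all 100 splits had to give as many and that comparison decides nothing. The highest of the others gave 3.

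Genes of skeletal muscle, thymocytes and atrial muscle moved between pools, and not together: the correlations between the 3 marker means lay between -0.227 and 0.00364. Over the 12 pools, the mean of 9 further skeletal markers followed that of the first 15 with r = 0.758 (permutation p = 0.00489, adjusted 0.00978; rho = 0.650, p = 0.0251, adjusted 0.0502), falling to 0.477 without the 2 farthest pools, and that of 11 further thymocyte markers followed the first 5 with r = 0.935 (p = 4e-05, adjusted 0.0002; rho = 0.902, p = 0.00015; 0.816 without the 2 farthest), which is consistent with pieces of muscle and thymus carried over at dissection. Among the further skeletal markers, Myoz1 and Actn3 were highest in CT34 (747 and 383), but Myh8 in CT42 (230) and Phka1 in CT46 (194). Fbp2 and Cacna1s lay at the floor in 7 of 12 pools each, and Cacng1 and Sgca in 5 each. The further thymocyte markers did not all move alike either. Cd8b1 and Satb1 measured 585 and 1053 at CT18 against -20.6 and 65.4 at CT26. Ptcra rose from 88.4 to 184 between these pools, and Cd1d1 ranged only from 923 to 1336, so the mean leans on its wide-ranging members. For atrial muscle r was 0.354 (permutation p = 0.253, adjusted 0.405, and rho = 0.112, p = 0.732). Without the 2 farthest pools r was -0.16, which leaves carried-over atrium open. The first atrial markers followed a 24-h cosine with an unadjusted permutation p of 0.0250 that the further ones did not share (0.738). Noise of the arrays is argued against, since the largest Pearson correlation of a marker mean with it was 0.193 in size (r = -0.193 for atrial markers, permutation p = 0.549, adjusted 0.732 over the 8 relations tested; rho = -0.434, p = 0.164, adjusted 0.262), and without the 2 farthest pools r was 0.245 for skeletal, -0.262 for thymocyte and 0.191 for atrial markers. A 24-h rhythm of skeletal muscle genes stays open, because the first and second day correlated at r = 0.499 over 6 circadian times (exact one-sided p = 0.167), while CT18 exceeded CT42 by a median of 1.17 log2 in 14 of 15 markers.

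Heat shock and chaperone genes were highest in the pool CT18 on the first day and in CT42 and CT62 on the second. Array noise is argued against as the whole cause: the amplitude of the list mean was 0.310 ± 0.07 (SE) alone and 0.327 ± 0.08 with array noise. With the 3 tissue means as covariates it was 0.609 ± 0.12. The first atrial markers themselves followed a 24-h cosine (unadjusted permutation p = 0.0250, peak CT15.1). The fit with tissue therefore cannot separate tissue from the rhythm, and carried-over tissue stays open. With the tissue means and with array noise the list no longer passed after adjustment over lists (adjusted permutation p = 0.0697 and 0.0571). The amplitude did not shrink, and its own permutation p was 0.00303 and 0.00745, against 0.00546 without covariates. The 6 values of the first day and of the second correlated at r = 0.789 (exact one-sided p = 0.0444), but the list had been picked for its fit to a 24-h curve over both days, so this adds no independent evidence for circadian time. The cause stays open, and body temperature and activity were not analysed here.

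Centring arrays on their medians lowered the count of rhythmic probe sets from 26 to 5. The array medians followed the noise of the arrays (r = 0.851, permutation p = 0.00059, adjusted 0.00157; rho = 0.846, p = 0.0009; 0.750 without the 2 farthest pools), so centring may add the variation of background to every gene. The 75th percentile followed it as well (r = 0.915), so the count of 7 after scaling on it leaves this open. A 24-h rhythm in the amount of message was not detected in the medians (permutation p = 0.503, amplitude 0.0491 log2), but the test leaves it open.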
